A study of Mus musculus with 32 samples.

How the data were processed

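Total RNA of mouse cells, isolated with Trizol and RNeasy columns per the labels' protocols, was labelled as biotin cRNA and hybridised to Illumina bead arrays, 1 sample per array. For the 18 infected-cell arrays the authors deposited the mean bead intensity per probe as exported by BeadStudio 3.2.6 from MouseWG-6 v1.1 arrays, with no normalization, per the file headers. Beside each intensity the deposited export gave a detection value, a fraction that was high where a probe was bright and was therefore read as 1 minus a detection p. The authors also deposited a table of normalized intensity for all 32 arrays, on a linear scale, by a method not given in the sources used here. In it each infected-cell column was a rising function of the same array in the export, and the OSKM 3 dpi replicate 1 column equalled its exported values within 0.05 intensity units. The 14 arrays of ESC, iPSC and uninfected MEF were used from this table alone, and had no detection values. Its column medians were 75.4 to 81.1 for infected cells and 56.1 to 61.6 for the others, so the sets were treated as normalized separately: tests were made only within each set, and no infected-cell level was set beside an uninfected one. Of the 46632 lines it held, 46621 (all but 11, at a tolerance of 0.01 in log2 distance) matched 1 probe of the 46643 in the export. The table, assumed to hold log2 values, proved linear and was put on the log2 scale for the same tests. Its centring stayed unknown.

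ESC (line v6.4) and iPSC were grown on mitomycin C-treated MEF feeders with LIF, and uninfected MEF came from embryos of an Actin-GFP or Pou5f1-GFP father and mothers of different strains, per the labels' protocols. The iPSC and ESC samples can therefore hold feeder RNA. N2OSKM 7 dpi replicate 3 and N2OSKM 11 dpi replicate 3 each had 1 label field that said 3 dpi, against the rest of their labels, and were kept in the groups of their titles.

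Infected-cell intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, using the detection p and an offset of 16, and put on the log2 scale. Probes were kept with a detection p under 0.05 on at least 3 arrays, and each gene was represented by its kept probe of highest mean signal, leaving 15876 genes. The deposited intensities of the other arrays were put on the log2 scale with no filter, leaving 32082 genes. Probe names were updated through the RefSeq gene table of the mouse assembly GRCm38.p6, used for names alone, 25196 probes by current symbol and 9191 by synonym, while 12042 found no match and 214 an ambiguous one and kept their array name. Of genes called at 11 dpi 180 had several kept probes, of which 149 had all probes of 1 sign, and no other probe of a called gene was called in the opposite direction on any day or averaged. A gene whose probes were undetected on every array of a group had only a bound there, given as "at least": the bright group's mean against the higher, per array, of the dim probe's own signal and the lowest signal of a detected probe. Log2 differences carry the standard error (SE) of the fit, and levels the SD between arrays.

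Linear models with group means only (lmFit and eBayes) were fitted to each set of arrays as a whole, so that all groups shared 1 estimate of spread per gene. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The median SE of a difference between groups was 0.162 for infected cells (12 residual and 6.52 prior degrees of freedom) and 0.0882 for the others (7 and 10.7). Day dependence was an F test of both cocktail-by-day terms. Lists were tested with camera (preset correlation of 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. The 22 lists covered the reprogramming factors, pluripotency, epithelial, mesenchymal and matrix, smooth muscle, cell cycle, p53 and senescence, interferon response, NR5A target, endoderm, trophoblast, neural, mesoderm and striated muscle, keratinocyte, macrophage and leukocyte, endothelial, adipocyte, germ cell, cholesterol biosynthesis, glycolysis, imprinted and sex-linked genes, and no gene stood in more than 1. The score of ESC-high minus MEF-high genes was tested by exact permutation of cocktail labels. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the plots.

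Genes were named by a rule: the 5 factors, the 8 largest rises and falls among genes past the threshold whose groups did not overlap on any array (10% of unchanged genes would not overlap with 3 arrays against 3), the 6 lowest adjusted p for day dependence, and up to 4 members of each list with the lowest adjusted p. 1 gene that the rule named is not reported here. Groups, comparisons, lists, this rule and the alternatives were fixed before the data were examined, except for restricting the lines to the brighter 50% of genes and comparing single N2 lines with iPSC OSKM and single probes of the factors between lines, which were added afterwards. The alternatives were the deposited normalized values, quantile normalization without background correction, an offset of 50, median scaling, other detection filters, averaged probes, a trended robust variance, fits of only the groups compared, the replicate number as a block and leaving out single arrays or both arrays with conflicting labels, and for the score a 4-fold difference between ESC and MEF and the omission of the 5 factors.

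In the infected cells the replicate number was the slide, and each of the 3 slides held all 6 groups. Deviations from group means correlated between same-numbered arrays with a mean r of 0.281 (45 pairs, 0.0177 to 0.638, 39 over 0.1) and all 18 arrays were closest to their own number, so the slide was tested as a block. For N2OSKM against OSKM on each day all 3 pairs exceeded 0.1.

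The procedure was tested on simulated data with 200 changed genes. For N2OSKM against OSKM at 7 dpi (15876 genes) it recovered 50.7%, 88.1% and 100% of genes changed 1.5-, 2- and 4-fold, and 15 of 174 calls were false (8.62%). Averaged over days these were 86.6%, 100% and 100%, with 8 of 199 calls false (4.02%). For iPSC OSKM against ESC (32082 genes) they were 86.6%, 98.5% and 100%, with 11 of 201 false (5.47%).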

Results

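Gene expression was measured on 32 Illumina bead arrays during the reprogramming of mouse embryonic fibroblasts (MEF) towards induced pluripotent stem cells (iPSC). MEF were infected with OSKM, the reprogramming factors Pou5f1 (Oct4), Sox2, Klf4 and Myc, or with N2OSKM, which added the orphan nuclear receptor Nr5a2, and were harvested 3, 7 and 11 days post infection (dpi). Each cocktail and day had 3 arrays, 18 in all. The other 14 arrays held 2 each of embryonic stem cells (ESC), 4 iPSC lines, and uninfected MEF carrying an Actin-GFP or a Pou5f1-GFP transgene. The iPSC lines were made with OSKM, with Nr5a2 in place of Pou5f1 (N2SKM), or with Nr5a2, Sox2 and Klf4 alone (N2SK lines B3 and B11). On the infected-cell arrays between 16460 and 19968 probes were detected, 35.3% to 42.8% of those printed. Replicates correlated with r of at least 0.977 across genes on these arrays and at least 0.996 among the 14 others. The first principal component held 58.8% of the variance of the infected-cell arrays and ordered them by day. Replicates were titled biological, but nothing stated that they came from separate cultures, so p-values measured only the spread between these samples, which may be technical. The number of arrays limited the precision.

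Of the factors, Nr5a2 was higher in cells that had received it. Its detected probe had a mean log2 signal of 5.68 ± 0.05 with N2OSKM and 4.71 ± 0.22 with OSKM at 7 dpi (SD, n = 3 arrays), and 5.95 ± 0.23 against 4.75 ± 0.06 at 11 dpi. These differences were at least 1.58-fold (adjusted p = 6.3e-04) and at least 1.98-fold (adjusted p = 5.2e-05), bounds because the probe was detected on none of the OSKM arrays. At 3 dpi it was detected on 2 of 3 N2OSKM arrays and no OSKM array, and the difference did not pass the test (adjusted p = 0.37). A second Nr5a2 probe and a second Sox2 probe were detected on no infected-cell array. Both were higher in ESC than MEF (2.52 and 3.45), so neither showed the delivered copies. Pou5f1, the core pluripotency factor shared by both cocktails, was 1.97-fold higher with N2OSKM at 11 dpi (9.06 ± 0.23 against 8.08 ± 0.15; adjusted p = 0.0025) but differed by -0.34 and 0.14 at 3 and 7 dpi. Sox2, Klf4 and Myc passed the test on no day, with log2 differences at 11 dpi of 0.41 ± 0.13, 0.03 ± 0.15 and -0.20 ± 0.16, although Sox2 passed at 11 dpi without the 2 arrays with conflicting labels (0.49, adjusted p = 0.028). With the authors' deposited values the Nr5a2 differences were 0.45 at 7 dpi and 0.56 at 11 dpi. Whether the probes used lay within the delivered coding sequences was not given.

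N2OSKM was compared with OSKM at each day, where Nr5a2 could not be told from culture or infection. At 3 dpi Prss35, which encodes a serine protease-like secreted protein, was higher in N2OSKM than in OSKM cells (7.26-fold; log2 difference 2.86 ± 0.15, SE, n = 3 arrays per cocktail; adjusted p = 7.9e-10). So were the mitochondrial protein genes Efhd1 (6.95-fold) and Chchd10 (6.04-fold), and Msc, a basic helix-loop-helix transcription factor (5.64-fold). The alcohol dehydrogenase genes Adh7 and Adh1 were 5.28-fold and at least 2.46-fold higher, and Clu, a secreted chaperone, by 1.44 ± 0.17. Keratin genes were lower, Krt14 of basal keratinocytes 4.32-fold and Krt6a 2.43-fold, as were the long noncoding RNA Miat (4.21-fold), the sialomucin gene Podxl (-1.68 ± 0.23) and the desmosomal plakophilin Pkp1 (-1.27 ± 0.17). In total 70 of 15876 genes passed the test, 41 higher and 29 lower.

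Of the fixed gene lists, keratinocyte genes were lower with N2OSKM at 3 dpi (2 of 9 measured members, 2 adjusted over the list alone; camera adjusted p = 3.4e-06). Imprinted genes were higher (2 of 11, 3 adjusted over the list alone; adjusted p = 3.4e-06), with Dlk1, a Notch-related growth regulator, up 2.02-fold and the cell-cycle inhibitor Cdkn1c up by 0.66 ± 0.12. The Cdkn1c call ended without N2OSKM replicate 1 or 2 or OSKM replicate 2 or 3 (adjusted p from 0.057 to 0.083) and when only the groups compared were fitted (0.062). The cell cycle list was shifted down by a median of -0.27 (adjusted p = 6.4e-11), although none of its 23 members passed alone, over the list alone either. All 70 genes kept their sign on each of the 3 slides, which 29.3% of all genes did. With arrays scaled to a common median in place of quantile normalization, 20 genes passed, 9 higher and 11 lower, and Adh1, Dlk1 and Cdkn1c did not. With the deposited values Adh1, Clu, Krt6a and Pkp1 passed with smaller differences of 0.74, 0.71, -0.69 and -0.65.

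At 7 dpi Cd3g, a T-cell receptor subunit gene, and Idi2, an isopentenyl diphosphate isomerase, were at least 15.6-fold and at least 17.4-fold higher with N2OSKM. Cd3g had a mean log2 signal of 8.98 ± 0.05 with N2OSKM and 4.35 ± 0.00 with OSKM, where it was not detected (adjusted p = 4.5e-16). Trh, the thyrotropin-releasing hormone precursor, was 11.1-fold higher, the kinase gene Stk32a 8.21-fold and Adh1 11.7-fold. The kallikrein genes Klk1 and Klk1b26 were 3.33 ± 0.23 and 3.28 ± 0.30 higher, and the aldo-keto reductase Akr1cl at least 5.86-fold, values that are uncertain because each belongs to a family of near-identical paralogs. Msln, a mesothelial surface protein, was 6.37-fold lower, Krt14 4.18-fold and Wfdc2, a secreted epithelial protein, 6.08-fold, and the hemidesmosomal integrin Itgb4 and the natriuretic peptide Nppb were lower, at -2.03 ± 0.16 and -1.96 ± 0.18. With the deposited values Adh1 and Akr1cl differed by 2.27 and 1.85, and with probes averaged Klk1b26 and Itgb4 differed by 1.55 and -0.93. In total 438 genes passed, 273 higher and 165 lower.

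Pluripotency genes were higher at 7 dpi (4 of 24, 5 adjusted over the list alone; adjusted p = 4.4e-04, and adjusted p = 0.35 with an estimated correlation). Among them were Jam2 (1.15 ± 0.23), Fbxo15 (0.88 ± 0.17), Tfcp2l1 (0.70 ± 0.17) and the Polycomb component Phc1 (0.69 ± 0.12). Tfcp2l1 did not pass with the deposited values (0.37, adjusted p = 0.081), with quantile normalization alone (0.41, adjusted p = 0.070) or with no detection filter (adjusted p = 0.055). The cell cycle list was now higher, with Cdk1 (0.73 ± 0.15) and Aurka (0.60 ± 0.15) past the test and 12 of 23 adjusted over the list alone (adjusted p = 1.5e-11). Of 15 p53 and senescence genes the cell-cycle inhibitors Cdkn1a (-0.58 ± 0.14) and Cdkn2b (-0.45 ± 0.12) were lower (3 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.18 with an estimated correlation). Imprinted genes were again higher, led by Dlk1 (3.75-fold; 2 of 11, 3 adjusted over the list alone; adjusted p = 4.9e-06). The macrophage list had a median of 0.24 with no member past the test, over the list alone either (adjusted p = 0.014, and adjusted p = 0.62 with an estimated correlation). The keratinocyte list was not called (adjusted p = 0.083, but 0.049 with an offset of 50 and 0.028 with median scaling), its median of 0.11 differing in sign from its mean of -0.38, although Krt14, Krt6a (-1.22 ± 0.15, but -0.58 with the deposited values and -0.60 with probes averaged) and Krt17 (-1.25 ± 0.23) were lower. Leaving out OSKM 7 dpi replicate 1 ended the calls of Tfcp2l1, Cdk1, Aurka, Cdkn1a and Cdkn2b (adjusted p = 0.12, 0.056, 0.089, 0.10 and 0.17). Each of the other 5 arrays ended at least 1 of them, and leaving out both arrays with conflicting labels ended Tfcp2l1, Cdk1 and Cdkn1a (0.068, 0.059 and 0.11). With median scaling 188 genes passed (145 higher, 43 lower), these 5 genes, Jam2 and Phc1 did not, and the macrophage call was lost (adjusted p = 0.058). Fitting only the groups compared gave 216 genes, without Fbxo15, Krt17, Cdk1, Aurka, Cdkn1a and Cdkn2b, and the slide as a block gave 670.

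At 11 dpi the genes highest over OSKM were Cd3g (at least 12.5-fold), Trh (18.3-fold; mean log2 signal 10.25 ± 0.38 against 6.06 ± 0.57), the acute-phase gene Saa1 (14.1-fold) and Kctd14 (11.6-fold). Stk32a was 10.7-fold higher, and the cytochrome P450 gene Cyp2s1 and Vat1l by 2.88 ± 0.20 and 2.79 ± 0.20. Krt14 was 4.79-fold lower, Krt6a at least 3.84-fold, and the epidermal growth factor family member Epgn, the matrix protein gene Prelp and the peptidase Dpp4 were lower, at -1.64 ± 0.16, -1.61 ± 0.17 and -1.53 ± 0.15. With the deposited values Cd3g, Saa1, Krt6a and Epgn passed at 2.80, 2.53, -1.16 and -0.83, and with probes averaged Krt6a and Dpp4 were at -1.21 and -0.69. In total 674 genes passed, 399 higher and 275 lower.

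Of 24 measured pluripotency genes, 11 were higher with N2OSKM at 11 dpi and none lower (11 adjusted over the list alone; adjusted p = 1.2e-09, and adjusted p = 0.056 with an estimated correlation). They included the DNA methyltransferase Dnmt3b (2.80-fold), the Nodal antagonist Lefty2 (at least 1.94-fold), Tfcp2l1 (1.24 ± 0.17) and Phc1 (1.06 ± 0.12). Mesenchymal and extracellular matrix genes were lower (3 of 32, 10 adjusted over the list alone; adjusted p = 8.8e-10). Col1a1, which encodes type I collagen, differed by -0.72 ± 0.13 and the transcription factors Prrx1 and Twist1 by -0.57 ± 0.13 and -0.54 ± 0.13. With probes averaged Prrx1 did not pass (-0.30, adjusted p = 0.22), and Twist1 did not without both arrays with conflicting labels (adjusted p = 0.063). Smooth muscle genes were lower too (3 of 9, 4 adjusted over the list alone; adjusted p = 1.9e-05), led by the actin-binding protein gene Tagln (-0.92 ± 0.13) and the smooth muscle actins Actg2 (-0.80 ± 0.14) and Acta2 (-0.43 ± 0.11). Keratinocyte genes were also lower (3 of 9, 4 adjusted over the list alone; adjusted p = 4.0e-07). Glycolysis genes were higher (2 of 12, 5 adjusted over the list alone; adjusted p = 4.0e-07), with phosphofructokinase Pfkp at 0.60 ± 0.13 and hexokinase Hk2 at 0.51 ± 0.11. Lefty2 and Tagln were at 0.61 and -0.53 with the deposited values, and with probes averaged Acta2 was at -0.70. Single arrays ended the calls of Acta2 (adjusted p = 0.14 and 0.064 without N2OSKM 11 dpi replicates 2 and 3, 0.087 and 0.13 without OSKM 11 dpi replicates 1 and 3) and Twist1 (0.12 without N2OSKM replicate 3, 0.13 and 0.096 without OSKM replicates 1 and 2). They also ended those of Prrx1 (0.061 without N2OSKM replicate 1, 0.053 without OSKM replicate 3) and Hk2 (0.058 without N2OSKM replicate 2).

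The 5 factors as a list were higher at 11 dpi (adjusted p = 0.0021, and adjusted p = 0.12 with an estimated correlation). Of these 2 passed, 3 over the list alone, and Nr5a2 was delivered with N2OSKM alone. Imprinted genes, where Dlk1 alone passed (0.78 ± 0.13, also over the list alone), were higher as a list (adjusted p = 0.020, and adjusted p = 0.12 with an estimated correlation). So was cholesterol biosynthesis (median 0.16, adjusted p = 0.024, and adjusted p = 0.12 with an estimated correlation). The cell cycle median was 0.13 (adjusted p = 0.046, and adjusted p = 0.34 with an estimated correlation). The macrophage median was -0.29 (adjusted p = 0.015, and adjusted p = 0.51 with an estimated correlation). No member of the cholesterol, cell cycle and macrophage lists passed, over the list alone either. Epithelial, interferon response, NR5A target, endoderm, trophoblast, neural, mesoderm and striated muscle, endothelial, adipocyte, germ cell and sex-linked lists were called on none of the 3 days, with adjusted p from 0.225 to 0.994. Among these, median, mean and test differed in sign for the NR5A target and mesoderm lists at 3 dpi and the endoderm, endothelial and sex-linked lists at 11 dpi. Within them single genes passed at 11 dpi, among them Krt7 (-1.28 ± 0.26) and Piwil2 (1.01 ± 0.19), a germ-line Argonaute gene that was at 0.49 with the deposited values and 0.67 without both arrays with conflicting labels. Median scaling left 240 genes (168 higher, 72 lower), not among them Col1a1, Prrx1, Twist1, Acta2, Pfkp, Hk2 and Dlk1, and ended the cell cycle, cholesterol and imprinted calls. The slide as a block ended the cell cycle call (adjusted p = 0.058). Fitting only the groups compared gave 440 genes, without Twist1, Acta2, Pfkp, Hk2, Krt7 and Piwil2, and leaving out N2OSKM 11 dpi replicate 2 gave 437.

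**Figure D1:**
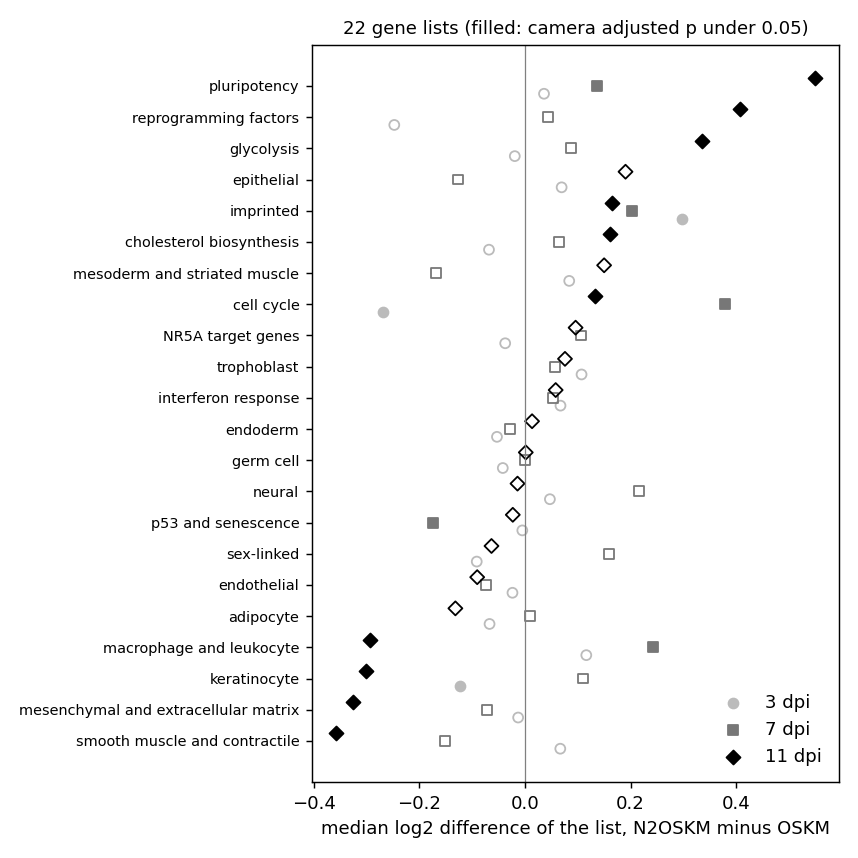
Median log2 difference, N2OSKM minus OSKM, of the measured members of each of 22 gene lists (vertical axis) at 3, 7 and 11 dpi (horizontal axis in log2 units). Filled points are lists with a camera adjusted p under 0.05. The cell cycle list lay at -0.27 at 3 dpi and 0.38 at 7 dpi, and the pluripotency list at 0.55 at 11 dpi.

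Averaged over the days, Efhd1 (2.77 ± 0.07), Adh1 (2.46 ± 0.10, not detected with OSKM at 3 dpi, and 1.52 with the deposited values), Stk32a (2.37 ± 0.09) and Prss35 (2.30 ± 0.09) were higher in N2OSKM cells and Krt14 (-2.15 ± 0.10), Msln (-1.84 ± 0.10) and Miat (-1.84 ± 0.10) lower (n = 9 arrays per cocktail). Genes past the test on each of the 3 days numbered 25 higher, among them Adh1, Adh7, Chchd10, Clu, Dlk1, the secreted signalling genes Bmp3 and Nmu and the kinase gene Prkcb. Another 10 were lower on each day, among them Krt14, Krt6a, Msln, Miat, Itgb4 and the progenitor surface marker Cd34. Between 7 and 11 dpi 153 genes were higher and 63 lower on both days, where independent lists would share 6.86 and 2.86. In total 760 genes passed, 436 higher and 324 lower. Pluripotency genes were higher (8 of 24, 9 adjusted over the list alone; adjusted p = 5.5e-08, and adjusted p = 0.085 with an estimated correlation). Imprinted (3 of 11 higher, 7 adjusted over the list alone; adjusted p = 1.0e-06) and glycolysis genes (1 of 12, 3 adjusted over the list alone; adjusted p = 0.0022, and adjusted p = 0.11 with an estimated correlation) were higher. Matrix genes were lower (3 of 32, with 7 lower and 1 higher adjusted over the list alone; adjusted p = 2.5e-05). Smooth muscle (2 of 9, 4 adjusted over the list alone; adjusted p = 0.0029) and keratinocyte genes (3 of 9, 3 adjusted over the list alone; adjusted p = 2.4e-05) were lower too. The cell cycle list, shifted in opposite directions at 3 and 7 dpi, had a median of 0.07 (adjusted p = 0.029, and adjusted p = 0.36 with an estimated correlation). With median scaling 293 genes passed (203 higher, 90 lower), and the cell cycle and glycolysis calls were lost (adjusted p = 0.25 and 0.10). The p53 and senescence list, at an adjusted p of 0.082, was called lower with the slide as a block (adjusted p = 0.045), the deposited values or quantile normalization (0.048 each).

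Whether the cocktail difference changed with time was tested. Cd3g and Idi2 were detected with neither cocktail at 3 dpi and with N2OSKM alone later, Cd3g at least 15.6-fold higher at 7 dpi and at least 12.5-fold at 11 dpi, and Idi2 at least 17.4-fold and at least 2.44-fold. Saa1, also undetected at 3 dpi, was at least 2.08-fold higher at 7 dpi and differed by 3.82 at 11 dpi, where 1 of 3 OSKM arrays detected it. Kctd14 differed by 2.05 at 7 dpi and 3.53 at 11 dpi, and the kallikrein Klk1b24 by 0.88 and 2.99, both detected on 1 of 3 OSKM arrays at 7 dpi and all 3 at 11 dpi. At 3 dpi Kctd14 was detected on 1 of 3 arrays of each cocktail and Klk1b24 on none. Stk32a, detected on every array, differed by 0.67, 3.04 and 3.41 at 3, 7 and 11 dpi (SE from 0.14 for Klk1b24 to 0.19 for Saa1). These 6 had the lowest adjusted p among 204 genes whose difference depended on day (F test of both cocktail-by-day terms, on measured signals whether detected or not). Between 3 and 11 dpi the change itself differed in 192 genes, 134 rising more or falling less with N2OSKM, with Trh at 4.03 ± 0.40 and Pou5f1 at 1.31 ± 0.26. The other way went 58, with Msc at -2.74 ± 0.25, Epgn at -1.56 ± 0.22 (measured signal, not detected with either cocktail at 3 dpi) and the skeletal actin Acta1 at -1.35 ± 0.18. Epgn and Acta1 were at -0.76 and -0.72 with the deposited values.

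By list, the change from 3 to 11 dpi was more positive with N2OSKM in the factors, Nr5a2 included (median difference 0.66, 1 of 5, 3 adjusted over the list alone; adjusted p = 8.6e-05). It was so too in pluripotency (0.53, 8 of 24, with 11 higher and 1 lower adjusted over the list alone; adjusted p = 1.0e-07, and adjusted p = 0.064 with an estimated correlation) and cell cycle genes (0.39, 0 of 23, 2 adjusted over the list alone; adjusted p = 5.9e-08). Glycolysis (0.31; 3 of 12 adjusted over the list alone; adjusted p = 2.4e-06) and cholesterol genes (0.25; adjusted p = 6.2e-04) moved the same way. It was more negative in matrix (-0.31, 3 of 32 adjusted over the list alone; adjusted p = 4.1e-07) and smooth muscle genes (-0.40, 1 of 9, 4 adjusted over the list alone; adjusted p = 4.2e-06). The same held for keratinocyte (-0.19, 1 of 9, 3 adjusted over the list alone; adjusted p = 0.020, and adjusted p = 0.055 with an estimated correlation) and macrophage genes (-0.41, no member over the list alone; adjusted p = 9.9e-04, and adjusted p = 0.42 with an estimated correlation). The slide as a block raised the counts to 313 (change from 3 to 11 dpi) and 399 (any day), and median scaling lowered them to 36 (32 and 4 by direction, without Acta1) and 43. The 192 genes fell to 112 without N2OSKM 11 dpi replicate 2, 126 without N2OSKM 3 dpi replicate 1, 125 and 118 without OSKM 11 dpi replicates 1 and 2, and 122 without OSKM 3 dpi replicate 2. The 204 fell to 131, 127 and 130 without N2OSKM 11 dpi replicate 2, N2OSKM 3 dpi replicate 2 and OSKM 11 dpi replicate 1.

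**Figure D2:**
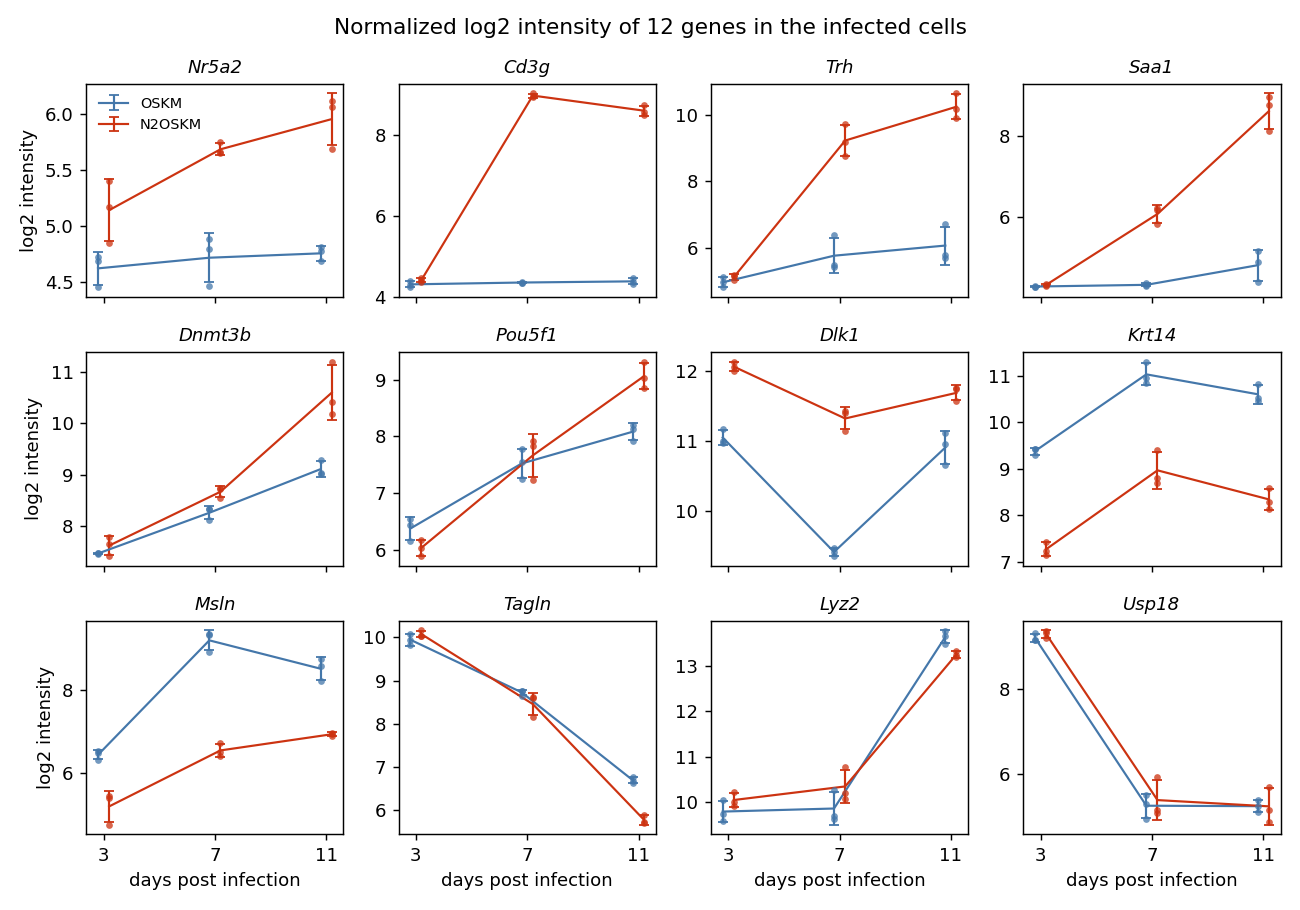
Log2 signal of 12 genes on each infected-cell array (points; vertical axis, log2 normalized intensity) at 3, 7 and 11 dpi (horizontal axis) with OSKM and N2OSKM. Lines join the group means and bars are SD of 3 arrays. Cd3g separated the cocktails at 7 and 11 dpi, while Lyz2 and Pou5f1 rose with both.

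To place infected cells between fibroblast and stem-cell expression, a score was taken as the mean of 1632 genes that passed the test and were at least 2-fold higher in ESC than in each of the 2 MEF preparations, minus the mean of 1275 genes higher in each preparation by the same rule. With OSKM it was -1.26 ± 0.01, -0.99 ± 0.06 and -0.60 ± 0.03 at 3, 7 and 11 dpi (SD, n = 3). With N2OSKM it was -1.34 ± 0.03, -0.88 ± 0.08 and -0.26 ± 0.03. N2OSKM minus OSKM was -0.08 at 3 dpi (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). It was 0.11 at 7 dpi (exact p = 0.2) and 0.34 at 11 dpi (exact p = 0.1). On the 3 slides the difference was -0.05, -0.11 and -0.07 at 3 dpi, 0.15, 0.13 and 0.05 at 7 dpi and 0.29, 0.38 and 0.35 at 11 dpi. Averaged over days it was 0.12 (two-sided exact p = 0.0358, permuting cocktail within day). The difference grew by 0.42 from 3 to 11 dpi (exact p = 0.005, the smallest that the 400 assignments allow). That permutation took the cocktails to be alike on both days and left the slides unpaired. The growth was not tested with the slide as a block. With the slide as a block the averaged difference no longer passed (exact p = 0.0938), nor did it without N2OSKM 7 dpi replicate 2 (0.11, exact p = 0.056).

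**Figure D3:**
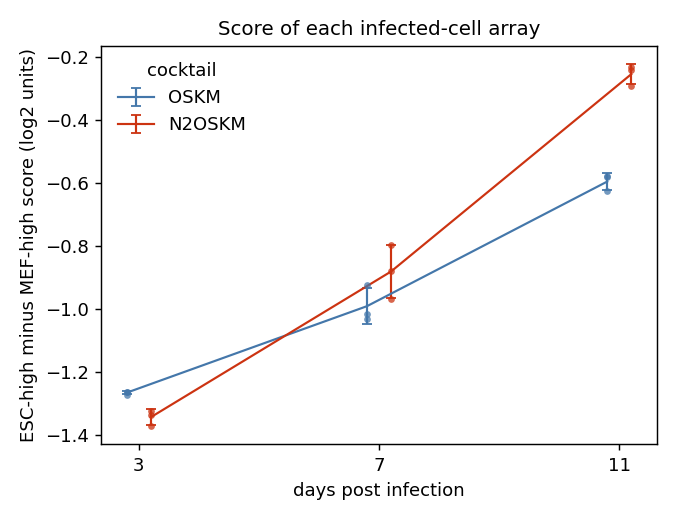
Score of each infected-cell array (points; vertical axis, mean log2 signal of ESC-high minus MEF-high genes) at 3, 7 and 11 dpi (horizontal axis) by cocktail. Lines join group means and bars are SD of 3 arrays. N2OSKM arrays had the higher mean at 11 dpi, -0.26 against -0.60.

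Within each cocktail changes were followed from 3 to 7, 7 to 11 and 3 to 11 dpi. From 3 to 11 dpi with OSKM, Saa3, an acute-phase serum amyloid, rose 170-fold (log2 difference 7.41 ± 0.24; adjusted p = 8.2e-14), haptoglobin (Hp) by 5.91 ± 0.30 and the lipoprotein gene Apoe by 5.59 ± 0.27. The tight junction gene Cldn11 rose by 5.73 ± 0.16, Prkcb at least 35.2-fold and the amino acid transporter Slc38a5 at least 36.6-fold, while Klk1 and Klk1b26, members of a family of near-identical paralogs, rose at least 80.5-fold and at least 35.9-fold. Falls included the interferon-induced protease Usp18 (-3.97 ± 0.21), the stress-induced gene Chac1 (-3.85 ± 0.24), the interleukin-33 receptor Il1rl1 (-3.68 ± 0.16) and the BMP antagonist Grem1 (-3.47 ± 0.15). Pou5f1 rose by 1.70 ± 0.18, Myc by 0.90 ± 0.16, Klf4 by 0.64 ± 0.15 and Sox2 by 0.62 ± 0.13. With the deposited values Myc was at 0.52, and with probes averaged Klk1b26 was at 2.81 and Il1rl1 at -1.47. Between 3 and 11 dpi 5187 genes changed (2669 up, 2518 down), against 1991 from 3 to 7 dpi (1084 up, 907 down) and 3233 from 7 to 11 dpi (1583 up, 1650 down).

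All 15 measured macrophage and leukocyte genes rose with OSKM from 3 to 11 dpi (15 adjusted over the list alone; adjusted p = 6.0e-19). The Fc receptor chain gene Fcer1g rose by 5.17 ± 0.21, complement C1qc by 5.03 ± 0.23 and lysozyme Lyz2 by 3.85 ± 0.19. Most of this rise came between 7 and 11 dpi, where the list's median was 3.26 (14 rose, 15 adjusted over the list alone; adjusted p = 4.5e-24). It was 0.34 from 3 to 7 dpi (6 rose, over the list alone too; adjusted p = 1.0e-04, and adjusted p = 0.34 with an estimated correlation). Interferon response genes fell from 3 to 7 dpi (18 of 21, over the list alone too; adjusted p = 1.2e-25), among them the chemokine Ccl5 (at least 4.43-fold lower, and -1.50 with the deposited values) and Usp18 (-3.96 ± 0.21). In part they rose again from 7 to 11 dpi (8, 12 adjusted over the list alone; adjusted p = 1.6e-05), leaving 13 below their 3 dpi level, over the list alone too (adjusted p = 6.4e-06). Smooth muscle genes fell at both steps (7 of 9 each, over the list alone too; adjusted p = 5.4e-10 and 1.6e-06), and from 3 to 11 dpi 8 fell, among them Tagln (-3.25 ± 0.13) and Myl9 (-2.79 ± 0.18). Matrix genes went both ways from 3 to 11 dpi, 16 of 32 lower, such as Prrx1 (-1.86 ± 0.13) and fibronectin Fn1 (-1.97 ± 0.15). Another 6 were higher, such as lumican Lum (3.73 ± 0.23) and Tgfbi (1.89 ± 0.14), in the same numbers over the list alone (adjusted p = 0.013 for lower, and adjusted p = 0.18 with an estimated correlation).

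Epithelial genes rose with OSKM from 3 to 11 dpi (12 of 16, over the list alone too; adjusted p = 1.3e-07), with the protease inhibitor Spint1 up by 3.56 ± 0.18 and the keratins Krt8 and Krt7 by 3.89 ± 0.22 and 3.59 ± 0.26. They rose at both steps, 5 from 3 to 7 dpi, over the list alone too (adjusted p = 2.3e-04, and adjusted p = 0.087 with an estimated correlation). From 7 to 11 dpi 9 rose (10 adjusted over the list alone; adjusted p = 8.8e-07). Cell cycle genes rose (17 of 23, 20 adjusted over the list alone; adjusted p = 3.2e-07), the kinetochore checkpoint gene Bub1b by 1.78 ± 0.20 and the survivin gene Birc5 by 1.15 ± 0.14. Of 24 pluripotency genes 10 rose and 3 fell, over the list alone too (adjusted p = 0.0051, and adjusted p = 0.28 with an estimated correlation), Fbxo15 by 4.58 ± 0.17 and the RNA-binding protein gene L1td1 by 3.80 ± 0.16 (smaller by over 1.5 times with the deposited values). Cholesterol genes rose (12 of 18, 13 adjusted over the list alone; adjusted p = 4.8e-05), and did so from 3 to 7 dpi (9, 12 adjusted over the list alone; adjusted p = 8.9e-08). The glycolysis (7 of 12 up, over the list alone too; adjusted p = 0.0012) and factor lists (4 of 5, over the list alone too; adjusted p = 0.0072) rose and the p53 and senescence list fell (8 of 15, with 1 up, over the list alone too; adjusted p = 0.0044). These 3 calls were lost with an estimated correlation (adjusted p = 0.089, 0.14 and 0.14). Among p53 targets Sesn1 rose by 3.89 ± 0.14 while Mdm2 and Plk2 fell (-1.67 ± 0.16 and -1.84 ± 0.15, with Mdm2 at -1.02 when probes were averaged). With probes averaged the Klf4 change no longer passed (0.13 with OSKM and 0.29 with N2OSKM), 1 of its 3 probes having fallen with both, and with median scaling it did not pass with OSKM. With median scaling 716, 1507 and 3027 genes changed from 3 to 7, 7 to 11 (990 up, 517 down) and 3 to 11 dpi.

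With N2OSKM the kallikreins Klk1 and Klk1b3 rose at least 179-fold and at least 116-fold from 3 to 11 dpi (again uncertain because of near-identical paralogs), Saa3 by 6.63 ± 0.24, the galectin Lgals7 by 5.64 ± 0.23 and Fbxo15 by 5.58 ± 0.17. The skeletal muscle actin Acta1 (-4.39 ± 0.13), Tagln (-4.30 ± 0.13) and the actin-binding Cald1 (-3.44 ± 0.27) fell. Pou5f1 rose by 3.02 ± 0.18, Sox2 by 1.27 ± 0.13, Klf4 by 0.98 ± 0.15, Myc by 0.83 ± 0.16 and Nr5a2 by 0.81 ± 0.15. With the deposited values Myc and Nr5a2 were at 0.45 and 0.38, and Tfcp2l1 at 1.78. Cd3g and Idi2 rose at least 15.4-fold and at least 17.2-fold from 3 to 7 dpi, and Idi2 then fell by 2.89. From 3 to 11 dpi 5948 genes changed (3041 up, 2907 down), with 2893 (1607 up, 1286 down) and 3483 (1718 up, 1765 down) at the first and second step.

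Pluripotency genes rose with N2OSKM from 3 to 11 dpi (15 of 24, with 3 lower, over the list alone too; adjusted p = 5.2e-05, and adjusted p = 0.14 with an estimated correlation). Dnmt3b rose by 2.98 ± 0.19, Tfcp2l1 at least 5.79-fold and, between 7 and 11 dpi, Nanog by 2.59 ± 0.32. Cell cycle genes rose (20 of 23, over the list alone too; adjusted p = 2.7e-10), most of them by 7 dpi (19, 21 adjusted over the list alone; adjusted p = 3.0e-15). So did epithelial (11 of 16, 12 adjusted over the list alone; adjusted p = 1.6e-07), glycolysis (10 of 12, 12 adjusted over the list alone; adjusted p = 1.3e-06) and cholesterol genes (13 of 18, 14 adjusted over the list alone; adjusted p = 1.3e-06). All 15 macrophage genes rose, over the list alone too (adjusted p = 3.3e-15), and 8 of 9 smooth muscle genes fell, over the list alone too (adjusted p = 9.6e-10). Matrix genes fell (21 of 32, with 4 up; over the list alone 21 and 5; adjusted p = 5.2e-05), among them the transcription factors Prrx1 (-2.44 ± 0.13) and Snai2 (-2.68 ± 0.23). Interferon genes fell (14 of 21, with 2 up, over the list alone too; adjusted p = 5.2e-05). Neural genes fell from 7 to 11 dpi (5 of 9, 6 adjusted over the list alone; adjusted p = 0.0022), led by Gap43 (-1.50 ± 0.16) and Ncam1 (-1.63 ± 0.23). The fall of p53 and senescence genes (9 of 15, with 1 up; over the list alone 9 and 2; adjusted p = 0.0087) was not called with an estimated correlation (adjusted p = 0.14). The rise of all 5 factors was called (adjusted p = 2.0e-04). Genes changing the same way from 3 to 11 dpi with both cocktails numbered 2231 up and 2133 down, where independent lists would share 511 and 461. Median scaling left 1349 (1024 up, 325 down), 1745 and 3626 genes for the 3 comparisons. It ended the epithelial call from 3 to 7 dpi, as did an offset of 50 (adjusted p = 0.071 and 0.068), and the factor and cell cycle calls from 7 to 11 dpi.

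ESC were compared with uninfected MEF. ESC had higher signal for the pluripotency regulators Esrrb (7.75 ± 0.07; n = 2 ESC and 4 MEF arrays; adjusted p = 3.1e-22), Nanog (6.59 ± 0.07) and Pou5f1 (5.60 ± 0.09), for Trh (7.51 ± 0.09) and for the methyltransferase cofactor Dnmt3l (7.48 ± 0.08). MEF had higher signal for the growth factor-binding protein Igfbp5 (log2 difference -7.45 ± 0.10), the heparin-binding cytokine Ptn (-6.97 ± 0.09) and the imprinted RNA H19 (-5.57 ± 0.11). These arrays had no detection values, so a group at background could not be told from one with low signal, and a difference against it can understate the change. Nr5a2, measured here by the probe not detected in infected cells, was higher in ESC by 2.52 ± 0.08. With probes averaged Esrrb, Ptn and Nr5a2 differed by 3.97, -3.51 and 1.27. All 34 pluripotency genes were higher, over the list alone too (adjusted p = 2.3e-41). So were 22 of 25 epithelial (22 higher and 1 lower adjusted over the list alone; adjusted p = 5.3e-15) and 24 of 26 cell cycle genes, over the list alone too (adjusted p = 4.1e-16). Matrix (31 of 32, over the list alone too; adjusted p = 5.2e-24) and smooth muscle (all 11, over the list alone too; adjusted p = 2.9e-08) genes were lower in ESC. So were cholesterol (17 of 19, 18 adjusted over the list alone; adjusted p = 4.6e-10) and macrophage genes (12 of 17 lower and 2 higher, with 13 lower and 2 higher adjusted over the list alone; adjusted p = 7.4e-06). In total 12717 of 32082 genes differed, 6267 higher and 6450 lower in ESC, and with a background offset of 50 they were 8910 and 4153.

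Each iPSC line was compared with ESC. The proteoglycan gene Dcn, a fibroblast matrix component, was higher by 6.06 ± 0.15 in N2SKM, 4.47 ± 0.15 in B3 and 4.81 ± 0.15 in B11 (n = 2 arrays per line), and Lum by 5.00 ± 0.11, 3.11 ± 0.11 and 3.60 ± 0.11. The iPSC OSKM line had higher smooth muscle actins Actg2 (3.10 ± 0.08) and Acta2 (2.24 ± 0.10) and the surface antigen Thy1 (2.18 ± 0.12). The simple-epithelium keratin Krt8 was higher by 3.24 ± 0.11 in B3 and 4.26 ± 0.11 in B11, together with Gsc (3.95 ± 0.09 and 3.49 ± 0.09), a transcription factor of the primitive streak, and T (Brachyury) was higher in all 4 lines. Among the delivered factors Klf4 was lower in each line (-0.82 ± 0.12 in OSKM, -1.14 ± 0.12 in N2SKM, -2.31 ± 0.12 in B3 and -2.12 ± 0.12 in B11) and Sox2 too (-0.79, -0.61, -1.28 and -1.35). A second Sox2 probe placed the lines differently, at -2.43 ± 0.15, -0.32 ± 0.15, -1.17 ± 0.15 and -1.15 ± 0.15 (SE), which did not pass in N2SKM (adjusted p = 0.16 over all probes). In iPSC OSKM the other Klf4 probes differed by -0.56 ± 0.11 and -0.19 ± 0.13 (adjusted p = 0.41 for the latter). Nr5a2 was lower in B3 (-1.12 ± 0.10). The probe detected in infected cells was at -0.06 there and passed in N2SKM alone (0.23, adjusted p = 0.032 over all probes). Pou5f1 was lower in B11 (-0.38 ± 0.10; adjusted p = 0.13 and 0.072 without ESC or B11 replicate 2) and passed in no other line. A second Pou5f1 probe passed in none (-0.36 ± 0.13 in B11, adjusted p = 0.073, and 0.26 ± 0.13 in N2SKM, adjusted p = 0.20 over all probes). In N2SKM the first, at -0.19, did pass without N2SKM replicate 2 (-0.36; adjusted p = 0.028) and with quantile normalization (-0.30; adjusted p = 0.032), but Pou5f1 was at 0.04 with probes averaged (adjusted p = 0.86). With probes averaged Dcn was higher by 2.70 in B3 and 2.89 in B11, Krt8 by 1.61 and 2.07, Thy1 by 1.12 in OSKM, and Nr5a2 was at -0.59 in B3. Counts were 7136 genes in OSKM (3754 higher, 3382 lower), 7161 in N2SKM (3732 and 3429), 6471 in B3 (3024 and 3447) and 6672 in B11 (3173 and 3499). Of these 1020, 793, 795 and 749 differed by at least 2-fold.

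Cholesterol biosynthesis genes were higher than in ESC in every line, 16 of 19 in all 4, with the synthase Hmgcs1 higher by 1.33 ± 0.07, 1.44 ± 0.07, 1.72 ± 0.07 and 1.61 ± 0.07 in OSKM, N2SKM, B3 and B11. The list counts were 16, 18, 18 and 17, and 17, 18, 18 and 18 adjusted over the list alone (adjusted p = 1.8e-12, 7.3e-23, 2.2e-26 and 1.2e-24). Of 34 pluripotency genes 12 were lower in all 4 lines, among them Nanog, Esrrb, Klf2 and Tbx3, and Dnmt3b was higher in all. The list was lower in each line (16 lower and 4 higher in OSKM, 17 and 6 in N2SKM, 28 and 3 in B3, 27 and 3 in B11; adjusted p = 3.5e-06, 7.4e-04, 8.8e-22 and 1.4e-19). Adjusted over the list alone these counts were 18 and 6, 20 and 6, 28 and 3, and 29 and 3. Esrrb differed by -1.55 ± 0.08, -2.53 ± 0.08 and -2.06 ± 0.08 in N2SKM, B3 and B11, and Tfcp2l1 by -1.98 ± 0.08, -2.09 ± 0.08 and -1.73 ± 0.08. With probes averaged Esrrb differed by -0.91, -1.34 and -1.08. Of 16 p53 and senescence genes 7 were higher in all 4 lines, among them Cdkn1a (2.01 ± 0.12, 1.52 ± 0.12, 1.15 ± 0.12 and 1.29 ± 0.12), and Gadd45a was lower. The list was called in each line (11, 11, 9 and 10 higher, 1 lower in each, over the list alone too; adjusted p = 1.2e-06, 3.0e-07, 1.5e-04 and 2.7e-06). In B3 and B11 it was not called with an estimated correlation (adjusted p = 0.084 and 0.051).

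Matrix genes were higher in OSKM (27 of 32, 28 adjusted over the list alone; adjusted p = 3.8e-22) and N2SKM (24, 26 adjusted over the list alone; adjusted p = 7.1e-21). They were higher in B11 (16, with 2 lower; over the list alone 17 and 3; adjusted p = 9.5e-11, and adjusted p = 0.080 with an estimated correlation), and were not called in B3 (adjusted p = 0.12). Endoderm genes were higher in B3 (6 higher and 1 lower of 17, 6 and 3 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.084 with an estimated correlation), with Sox17 at 1.99 ± 0.10 and Foxa2 at 1.79 ± 0.08 (0.93 with probes averaged). They were called in B11 too (5 and 2, 5 and 3 adjusted over the list alone; adjusted p = 0.0080, and adjusted p = 0.080 with an estimated correlation). The macrophage list, with Lyz2 higher by 3.70 ± 0.14 in N2SKM and 2.87 ± 0.14 in B11, was called in both (7 higher and 2 lower of 17 in each, 8 and 2 in N2SKM and 7 and 2 in B11 adjusted over the list alone; adjusted p = 6.0e-04 and 0.040). In B11 the call was lost with an estimated correlation (adjusted p = 0.11) and with quantile normalization, an offset of 50 or median scaling (adjusted p = 0.073, 0.081 and 0.056). With probes averaged Lyz2 was at 1.23 and 0.94. The list's median of -0.00 differed in sign from its mean of 0.25 and from the test. Germ cell genes were called lower in OSKM, B3 and B11 (4, 3 and 4 of 11, 4, 3 and 4 adjusted over the list alone; adjusted p = 0.019, 0.038 and 0.040). They were called in none with an estimated correlation (adjusted p = 0.13, 0.25 and 0.17) or with quantile normalization (adjusted p = 0.073, 0.056 and 0.053). Epithelial genes were lower in iPSC OSKM (16 of 25, with 1 higher, over the list alone too; adjusted p = 3.5e-12), with Rab25 at -2.07 ± 0.08 and Spint1 at -1.98 ± 0.08. The steroidogenic enzyme gene Cyp11a1 of the NR5A target list was higher in each line (0.71 ± 0.09, 1.68 ± 0.09, 0.63 ± 0.09 and 0.72 ± 0.09 in OSKM, N2SKM, B3 and B11). With probes averaged it was 0.18 in OSKM, where it did not pass, and 0.47, 0.22 and 0.26 in the others, and the list was called in no line.

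At least 2-fold, 51 genes were higher and 118 lower in all 4 lines, where independent lists would share 0.00101 and 0.000766. Part of this excess may come from the shared controls, which that value leaves out. At an unadjusted p under 0.05, 1626 genes were higher and 1895 lower in all 4. Means were 42.1 and 42.3 (at most 52 and 55) in 50 simulations of unchanged groups against the same ESC arrays. These left out traits of the ESC line, shared by all 4 tests. Differences from ESC correlated between lines with r from 0.501 to 0.885 across genes, which are not independent replicates, against 0.501 simulated, with covariances from 0.0654 to 0.107 against 0.00490 simulated. Each line was one line, so that line and factor set could not be told apart.

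**Figure D4:**
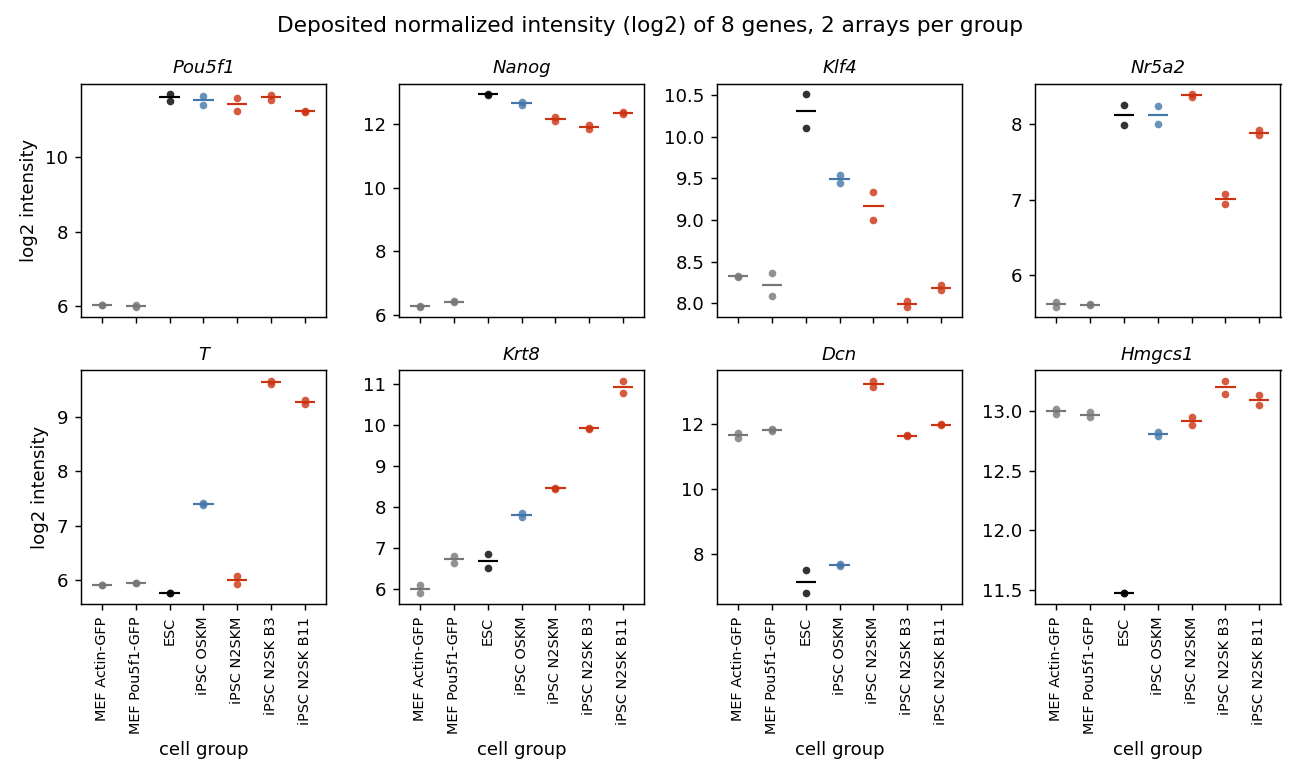
Log2 signal of 8 genes on each of the 14 arrays of ESC, 4 iPSC lines and 2 kinds of uninfected MEF (points, with log2 normalized intensity on the vertical axis, group on the horizontal axis and dashes for means of 2 arrays). Dcn lay above 11 in the 3 N2 lines and MEF and below 8 in ESC and iPSC OSKM.

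Against MEF the 4 iPSC lines together had higher Trh (7.51 ± 0.06; n = 8 iPSC and 4 MEF arrays), Dppa4, a pluripotency-associated chromatin protein gene (mean log2 signal 12.21 against 5.61), Pou5f1 (5.44 ± 0.06) and Nr5a2 (2.25 ± 0.06, but 0.06 with its other probe). They had lower Ptn (-5.31 ± 0.06), H19 (-4.63 ± 0.08) and elastin Eln (-4.17 ± 0.05). With probes averaged Nr5a2, Ptn and Eln differed by 1.15, -2.70 and -2.28. Of 34 pluripotency genes 33 were higher, over the list alone too (adjusted p = 1.4e-36), and of 32 matrix genes 30 were lower, over the list alone too (adjusted p = 3.5e-17). Smooth muscle genes were all lower, over the list alone too (adjusted p = 8.2e-07, and adjusted p = 0.060 with an estimated correlation). In total 19032 genes differed, 6727 higher and 12305 lower. With quantile normalization alone 12310 differed (6241 higher, 6069 lower), with median scaling 7515 were higher and 6257 lower, and with a background offset of 50 they were 12110 and 4217. Among the brighter 50% of genes, an alternative chosen after seeing the data, 11151 differed.

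The 3 N2 lines were compared with iPSC OSKM. They had higher Dcn (4.60 ± 0.12; n = 6 and 2 arrays), the chemokine Ccl11 (3.31 ± 0.08), Saa3 (3.76 ± 0.07) and the keratin Krt7 (2.56 ± 0.07). They had lower Smoc2 (-3.52 ± 0.11), a matricellular protein gene, lubricin Prg4 (-3.41 ± 0.06) and the metalloproteinase inhibitor Timp3 (-3.12 ± 0.07). With probes averaged Dcn, Smoc2, Prg4 and Timp3 differed by 3.06, -1.94, -1.82 and -1.71. Klf4 was lower in the mean of the 3 lines (-1.04 ± 0.10), as was Nr5a2 itself (-0.37 ± 0.08, but -0.25 without iPSC OSKM replicate 2, -0.23 with probes averaged and -0.08 with its other probe). The 2 Sox2 probes went opposite ways, -0.29 ± 0.08 and 1.55 ± 0.12 (adjusted p = 0.017 and 1.7e-08 over all probes). Line by line, a comparison added after these values were seen, Nr5a2 was lower in B3 (-1.12 ± 0.10) and differed by 0.26 ± 0.10 in N2SKM and -0.24 ± 0.10 in B11 (adjusted p = 0.080 and 0.097). Klf4 was lower in B3 (-1.50 ± 0.12) and B11 (-1.30 ± 0.12) and differed by -0.33 ± 0.12 in N2SKM (adjusted p = 0.081). Epithelial genes were higher (20 of 25, with 1 lower, over the list alone too; adjusted p = 2.1e-20), as were cholesterol genes (12 of 19, with 1 lower; over the list alone 15 and 1; adjusted p = 5.0e-10), and both lists were called in each single line, although in N2SKM not for cholesterol with an estimated correlation (adjusted p = 0.065). Pluripotency genes were lower (20 of 34, with 5 higher; over the list alone 20 and 6; adjusted p = 4.8e-05). By line they were lower in B3 and B11 (medians of -0.64 and -0.51; adjusted p = 1.3e-10 and 2.9e-08) but not in N2SKM (0.01; adjusted p = 0.61). Endoderm genes were higher (4 of 17, 5 adjusted over the list alone; adjusted p = 0.0021), with a median of -0.00 and a mean of 0.21. They were called in B3 and B11 (adjusted p = 0.0020 and 8.2e-04) and not in N2SKM (adjusted p = 0.53), with Sox17 at 1.72 and 1.21 in B3 and B11 and -0.17 in N2SKM (adjusted p = 0.24) and Foxa2 at 1.85, 1.49 and 0.10 (adjusted p = 0.42 for the last). Matrix genes (21 lower, 6 higher; over the list alone 22 and 6; adjusted p = 5.4e-05, and adjusted p = 0.23 with an estimated correlation) were lower, again in B3 and B11 (adjusted p = 7.6e-11 and 3.5e-04, and adjusted p = 0.071 and 0.29 with an estimated correlation) and not in N2SKM (adjusted p = 0.53). None of these differences between lines was tested directly. Smooth muscle genes were lower too (7 of 11, 8 adjusted over the list alone; adjusted p = 4.6e-06, and adjusted p = 0.099 with an estimated correlation), called in N2SKM, B3 and B11 but not with an estimated correlation (adjusted p = 0.10, 0.071 and 0.13). Macrophage genes were called higher (adjusted p = 0.029, but 0.074 with quantile normalization). They were so in N2SKM (adjusted p = 4.5e-05) and B11 (0.040, and 0.14 with an estimated correlation), not B3 (0.83). In total 6612 genes differed, 2922 higher and 3690 lower, a balance that median scaling turned (3443 and 2797), as did a background offset of 50 (3434 and 2793).

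Between the 2 MEF preparations, of different transgene and maternal strain, Actin-GFP MEF had higher Serpina3n (3.15 ± 0.11), an acute-phase protease inhibitor, and higher macrophage genes such as Lyz2 (2.28 ± 0.14) and Cd14 (2.00 ± 0.17). It had lower Adh7 (-3.37 ± 0.09) and collagen Col1a2 (-2.06 ± 0.12; n = 2 arrays each). Of 17 macrophage and leukocyte genes 12 were higher and 1, Fcer1g (-2.82 ± 0.08), lower, over the list alone too (adjusted p = 1.0e-21). Cholesterol genes were higher (8 of 19, 11 adjusted over the list alone; adjusted p = 7.9e-09), and the mesoderm and striated muscle list lower (5 of 13, over the list alone too; adjusted p = 9.1e-05). The Y-linked gene Eif2s3y was lower (-3.36 ± 0.12) and Xist, the X-inactivation RNA, higher (1.45 ± 0.10), so sex may differ too. With probes averaged Lyz2, Adh7, Eif2s3y and Xist differed by 0.82, -1.66, -1.70 and 0.77. In total 2276 genes differed, 757 higher and 1519 lower in Actin-GFP MEF. With quantile normalization alone they were 1216 and 1316, and single arrays left out gave 1504 (Actin-GFP replicate 2), 1415 (Pou5f1-GFP replicate 1) and 1505 (Pou5f1-GFP replicate 2).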

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

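The tests of other splits of the arrays, of fibroblast RNA, of the authors' normalization, of mislabelled arrays and of normalization for the macrophage genes were chosen only after the result was seen.

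The cocktail difference, with Nr5a2 and culture confounded, depended on day in 204 genes. The highest F statistics were for Cd3g (576), Idi2 (219), Kctd14 (138), Klk1b24 (115), Saa1 (95.8) and Stk32a (84.4). The change from 3 to 11 dpi differed between cocktails in 192 genes. By list the median difference of that change was 0.66 for the factors, 0.53 for pluripotency, 0.39 for cell cycle, 0.31 for glycolysis and 0.25 for cholesterol genes. It was -0.31 for matrix, -0.40 for smooth muscle, -0.41 for macrophage and -0.19 for keratinocyte genes. With an estimated correlation the pluripotency, macrophage and keratinocyte calls were lost (adjusted p = 0.064, 0.42 and 0.055). The cocktail difference in the score of ESC-high minus MEF-high genes grew by 0.42.

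With cocktail labels exchanged within days, the real split alone, 1 of 100 drawn, gave as many genes for day dependence (204, highest other 161), for the change from 3 to 11 dpi (192, highest other 141) and averaged over days (760, highest other 65). The split with 161 genes exchanged 2 of 3 labels at 3 and at 7 dpi and 0 at 11 dpi. With labels exchanged within slide and day, so that each split parted all slide pairs, 100 of 256 splits were drawn. As many genes came from 3 of them for day dependence (highest other 652), 2 for the change from 3 to 11 dpi (highest other 218) and 1 averaged over days (highest other 466), the real one included. All these shares of the splits drawn were under 0.05, but chance between cultures stayed open. The split with 652 genes, several times the real count, exchanged all 3 labels at 7 dpi and 1 at 3 dpi. Exchanging a whole day turns the cocktail difference of that day, so that genes with a like difference on all days (25 higher and 10 lower were called on each) count as dependent on day. The highest others of 218 and 466 genes each came with 2 of 3 labels exchanged at 3 dpi and 0 on later days. For the 4 iPSC lines against MEF the 15 splits of the 4 lines and 2 preparations were too few for a share under 0.05, with 19032 genes in the real split and 14669 in the highest other. For 3 arrays against 3 the 10 splits were too few for a share under 0.05. The genes differing between cocktails at 3, 7 and 11 dpi were 70, 438 and 674, against 0, 11 and 1 in the highest other split. Of these 10 splits 4, the real one included, parted all slide pairs, and the others of those gave 0 genes on each day. For changes with time within each cocktail the highest other split gave 0.

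Of 32 matrix genes 7 were higher than in ESC in all 4 iPSC lines, although the list was not called in B3 (adjusted p = 0.12), with Dcn at log2 means of 13.22 in N2SKM, 11.63 in B3 and 11.97 in B11 against 7.16 in ESC. In the 3 N2 lines fibroblasts like these MEF could not be judged as the whole source of the 7 genes as a set, since these were chosen for being higher. At most 12% of the 100 most abundant genes at least 4-fold higher in MEF than in ESC reached the share of MEF RNA the 7 genes needed. Medians were 52.1%, 22.4% and 29.7% in N2SKM, B3 and B11, against 14.1%, 2.98% and 11.0% for the abundant genes. By gene the needed share ran from 22.6% to 288% in N2SKM, 7.49% to 93.0% in B3 and 11.3% to 119% in B11. In N2SKM Dcn lay above these MEF (13.22 against 11.73), so such RNA alone could not give its level there. Some such RNA stayed open in the 3 N2 lines, since 86, 50 and 86 of the 100 abundant genes were higher than in ESC (3, 16 and 1 lower). For iPSC OSKM it stayed open as the source, since 82% of the abundant genes reached the median needed share of 8.61% (1.87% to 74.7% by gene). Acta2 gave 78.6%, so no 1 share held. Such RNA may come from the feeder layer. Scale or background left by the authors' normalization was argued against as the whole source in iPSC OSKM, N2SKM and B11. With quantile normalization or an offset of 50 on the deposited values the median of all 32 genes stayed above that of all genes (lowest difference 0.27, in B11). The list stayed called, but the B11 call was lost with an estimated correlation. In B3 this source stayed open, at a lowest difference of 0.00060 and no call. Feeders unlike these MEF, and differentiated cells in the cultures, were not tested.

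N2OSKM 7 dpi replicate 3 and N2OSKM 11 dpi replicate 3 each had a label field that said 3 dpi. On a scale from the 3 dpi mean (0) to the mean of the other 2 arrays of the group (1), the first lay at 0.907 over 719 genes and the second at 0.937 over 2165 genes, which argued against 3 dpi cells on either array. No biological explanation was tested.

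All 15 measured macrophage and leukocyte genes rose at least 2-fold from 3 to 11 dpi with both cocktails, Lyz2 from 9.79 ± 0.24 to 13.64 ± 0.14 (log2 mean ± SD, n = 3) and complement C1qc from 6.41 ± 0.23 to 11.45 ± 0.16 with OSKM. Normalization was argued against as the source, since the list's median rise was at least 2.88 under 4 other sets of values. RNA of macrophages in the dishes remained a candidate explanation, since the members' deviations from group means correlated (mean r = 0.579) more closely than in 100% of 1000 random lists of the same size and signal (highest 0.202). In uninfected MEF 12 of 17 of these genes were already higher than in ESC, and the labels named no sort that would remove macrophages. Expression of these genes by the infected cells themselves was not tested.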

How the results depend on the processing

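Using the brighter 50% of genes for the lines was chosen only after the result was seen. Apart from single arrays left out, 192 alternative values of the main results kept their direction and side of the threshold, or stayed within 1.5 times for counts, 20 counts moved further and 1 value no longer passed. With single arrays left out these were 171, 12 and 1. No result reversed. The deposited values, quantile normalization, an offset of 50, both detection filters, averaged probes, the trended variance and leaving out both arrays with conflicting labels moved no infected-cell count by over 1.5 times.

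Scaling each array to its median gave 20, 188, 240 and 293 genes for N2OSKM against OSKM at 3, 7 and 11 dpi and averaged. For changes with time it gave 716, 1507 and 3027 with OSKM and 1349, 1745 and 3626 with N2OSKM (3 to 7, 7 to 11 and 3 to 11 dpi). It gave 36 for the change from 3 to 11 dpi and 43 for any day dependence. All 20, 183 of 188, 238 of 240 and 291 of 293 genes of the cocktail comparisons were among those called by quantile normalization, and the cause of the lower counts was not tested. No scaling moved the median of all infected-cell genes by over 0.1 on the log2 scale (highest 0.096, at 7 dpi with median scaling). Fitting only the groups compared, which leaves fewer arrays to estimate the spread, gave 216 genes at 7 dpi and 440 at 11 dpi.

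The slide as a replicate block gave 670 genes at 7 dpi, 313 for the change from 3 to 11 dpi and 399 for day dependence, and kept the averaged score difference at 0.124 with an exact p of 0.0938 (0.0358 without it), and the cause was not tested. Of lists, this block ended the cell cycle call at 11 dpi (adjusted p = 0.058) and the adipocyte call with OSKM from 7 to 11 dpi (0.051), and added p53 and senescence averaged over days (0.045) and neural genes with N2OSKM from 3 to 11 dpi (0.045). The p53 and senescence list with N2OSKM from 7 to 11 dpi (0.057) was called lower under all 5 alternatives, this block (0.044) and 4 other sets of values (0.032 to 0.043). The block changed no other call of a list and no other count by over 1.5 times. In the lines and MEF replicates shared only a number (mean r = 0.0466 over 42 pairs, 12 over 0.1), although all 14 arrays correlated best with their own number, and the replicate block moved no count by over 1.5 times.

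Over 5 alternatives the adjusted p of lists called between cocktails at 11 dpi ran from 0.016 to 0.40 for cell cycle, 0.0084 to 0.20 for cholesterol and 0.0079 to 0.20 for imprinted genes, and at 7 dpi from 0.015 to 0.058 for macrophage genes. Averaged over days it ran from 0.0062 to 0.25 for cell cycle and 1.8e-04 to 0.10 for glycolysis genes, and from 0.045 to 0.054 for p53 and senescence, not called at 0.082 but called with the block, the deposited values and quantile normalization (0.048 each for the latter 2). Lists also gained calls, cholesterol lower at 3 dpi (0.037 to 0.14) and smooth muscle (0.037 to 0.27) and keratinocyte genes (0.028 to 0.32) lower at 7 dpi. Over 4 alternatives for the lines it ran from 1.7e-04 to 0.068 for matrix genes between MEF preparations and from 0.0027 to 0.71 for cholesterol genes in iPSC lines against MEF. No list changed direction, and the cause of these changes was not tested.

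For iPSC lines against MEF quantile normalization gave 12310 genes and the brighter 50% of genes 11151, the latter from fewer genes tested. Leaving out single arrays gave 437 to 549 genes at 11 dpi (437 without N2OSKM 11 dpi replicate 2), 112 to 207 for the change from 3 to 11 dpi, 127 to 214 for day dependence and 1415 to 1678 between MEF preparations. For the last 3 of these counts, each array whose omission is given in Results moved the count by over 1.5 times. The score difference was 0.110 to 0.138, 0.110 (exact p = 0.056) without N2OSKM 7 dpi replicate 2. Where 1 array of a pair was left out, the lone array was assumed to vary like the other groups. Detection filters and other values could not be tried for the lines and MEF, which had neither detection values nor exported intensities.

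For 255 differences of named genes 3953 alternative values were made, of which 3864 were the same in direction and side of the threshold, 80 no longer passed, 3 passed anew, 6 moved and 0 reversed, and 225 differences kept their call throughout. Median scaling ended 19 of these calls, fitting only the groups compared 13, averaging probes 4, leaving out both arrays with conflicting labels 4, and the deposited values, quantile normalization and no detection filter 1 each. Single arrays left out ended 12 calls (adjusted p from 0.053 to 0.20). Of called differences 51 moved by over 1.5 times on the log2 scale with probes averaged, 27 with the deposited values, 22 with quantile normalization and 19 with an offset of 50. The causes were not tested.

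Signal over background limited dim genes: at 7 dpi a simulated 2-fold change in raw signal was recovered as 0.96 on the log2 scale in brighter and 0.70 in dimmer probes.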

Other observations

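EGFP, a green fluorescent protein sequence on the array, and the genes Ddit3, Cth, Gdf15 and Txnip were chosen after their values were seen. EGFP had a mean log2 signal of 5.48 in ESC, 5.66 in Pou5f1-GFP MEF and 12.8 in Actin-GFP MEF, and between 13.3 and 14.3 in the iPSC lines (n = 2 arrays each). Against ESC it was higher by 7.86, 8.78, 8.55 and 8.66 in OSKM, N2SKM, B3 and B11 (limma adjusted p of at most 3.6e-20). The other 4 genes were lower than in ESC in all 4 lines. The stress-induced transcription factor Ddit3 differed by -1.44, -2.22, -1.35 and -1.94 in OSKM, N2SKM, B3 and B11, the transsulfuration enzyme Cth by -2.75, -2.36, -1.63 and -2.06, the cytokine Gdf15 by -1.34, -1.27, -1.20 and -1.38, and the thioredoxin inhibitor Txnip by -1.57, -1.57, -1.75 and -1.97.

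Olig1, Eif2s3y, Rpl29, Cbwd1 and Ipp were likewise chosen after their values were seen. The oligodendrocyte transcription factor Olig1 lay at 9.92 in ESC and between 5.88 and 6.43 in the iPSC lines and MEF. The Y-linked gene Eif2s3y lay at 5.63 in iPSC OSKM and 5.71 in Actin-GFP MEF, against 9.07 in Pou5f1-GFP MEF and 9.70 to 10.2 in ESC and the N2 lines. The ribosomal protein gene Rpl29 lay at 7.57 and 6.73 in iPSC OSKM and Actin-GFP MEF and at 10.7 to 11.1 elsewhere, and Cbwd1 at 7.04 and 7.25 in these, 8.93 in Pou5f1-GFP MEF and 9.98 to 10.3 elsewhere. Ipp lay at 12.2 in iPSC OSKM and 7.67 to 7.99 in all other groups.

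Whether genes higher with N2OSKM at 11 dpi are genes higher in ESC than in MEF was tested only after the result was seen, and whether they are further along the change that OSKM cells had begun was written down before. Of 399 such genes 163 (40.9%) were at least 2-fold higher in ESC than in the mean of both MEF preparations, against 11.8% of all genes, an odds ratio of 5.55 (95% confidence interval 4.49 to 6.85; two-sided Fisher's exact test, adjusted p = 9.0e-50, across genes, which are not independent replicates). Among those at least 2-fold higher with N2OSKM, 62 of 143 were ESC-high, 9 MEF-high and 72 neither. The neither group held Cd3g and Saa1, whose signal did not differ between ESC and MEF, while Trh was higher in ESC by 7.51. Of 275 lower genes 123 (44.7%) were MEF-high, against 9.66%. Of 41 genes higher at 3 dpi 16 (39.0%) were MEF-high (odds ratio 6.04, 95% confidence interval 3.00 to 11.8; adjusted p = 1.2e-06) and 9 ESC-high (odds ratio 2.11; adjusted p = 0.070), and of 273 at 7 dpi 57 were MEF-high (odds ratio 2.52; adjusted p = 4.8e-08) and 68 ESC-high (odds ratio 2.53; adjusted p = 5.1e-09). A hypothesis from these values is that part of the difference at 11 dpi lay along the difference between fibroblasts and ESC, while 72 of the 143 genes lay outside it; no technical explanation was tested.

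A faster passage along the OSKM course could not be told from another course. Differences at 11 dpi had a rank correlation across genes of 0.175 with the change of OSKM cells from 3 to 7 dpi, and of the 399 genes 108 had risen and 31 had fallen in that interval, with a median change of 0.16. The positive but low correlation kept the explanation open.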
